A study of Mus musculus with 22 samples.

How the data were processed

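Chromatin immunoprecipitation and sequencing (ChIP-seq) of whole testis was analysed in 22 libraries: 19 immunoprecipitations against γH2AX (histone H2AX phosphorylated at DNA damage and on unsynapsed chromosomes) or the histone variant H3.3, and 3 inputs. The deposited values are counts per 50 kb window, 54520 windows along the 21 chromosomes of mm10, 1 table per library. Per the submitters' processing notes, CASAVA 1.8 and BWA were used with mm10; settings, and whether duplicate or multiply mapping reads were removed, are not stated there. Window totals per library ran from 11876426 to 128348440 counts. The median count per window ran from 203 in the B6 input to 2030 in H3.3 Cg replicate 1, so counting error at the median window was 2.22 to 7.02%. Over 18 pairs of replicates the chi-square per degree of freedom ran from 1.20 to 28.7, so no replicate was a copy of another. Gene positions came from the GRCm38.p6 RefSeq table, the assembly of mm10: 21887 protein-coding genes, with 29835 windows overlapping at least 1.

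Groups were taken from the sample titles. The input titled 1Rb_M carries the strain label of the 1Rb_P cross; it was grouped by its title. Labels name replicates by number and do not say that each is a separate animal, so p-values measure only the spread between these samples. The carrier crosses differ from each other and from the controls in parental strains as well as in translocations, and H3.3 was measured at 6 weeks against 4 weeks for γH2AX. That 3Rb carries translocations joining 1 with 3, 8 with 12 and 9 with 14 is background knowledge on the RBF/Dnj strain, since the labels name only the 1Rb translocation, of 8 with 12.

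Groups, tests, gene lists and the rule for named windows were fixed before the data were examined. For each mark, the 9 libraries of the 3 replicated groups were fitted together with edgeR 4.0.16 (R 4.3.3): windows with a mean count of at least 10 over the 9 libraries, trimmed mean of M-values (TMM) scaling, quasi-likelihood test, Benjamini-Hochberg adjustment over windows, and an adjusted p under 0.05 as a call. This left 53117 windows for H3.3 and 53118 for γH2AX. The same test was run on counts summed per chromosome, adjusted over the 21 chromosomes, with the window scaling. Every "adjusted p" of a window or chromosome in the text is from edgeR unless another tool is named. CPM values are window counts scaled by edgeR to a common library size; they are given with their SD over 3 libraries, and log2 differences with their SE.

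Region enrichment was the log2 ratio of a library to the pooled 3 inputs in 7 regions, relative to the mean over the 13 autosomes in none of the 3 translocations (2, 4, 5, 6, 7, 10, 11, 13 and 15 to 19). The regions were X; Y; the proximal 10 Mb (3 to 13 Mb, next to the centromere) of 8 and 12, of 1, 3, 9 and 14, and of the other autosomes; and the rest of 8 and 12 and of 1, 3, 9 and 14. For the median window of a region of 1 chromosome, the profiles and the gene number correlations, 0.5 was added to each window count before the log2 ratio; sums over regions had no added count. Groups were compared with two-sided exact permutation tests (scipy 1.17.1), adjusted over the 7 regions; 3 libraries against 6 allow no p below 0.0238 and 3 against 3 none below 0.1. The B6 library has no replicate and a different antibody supplier label, so its position against the carriers was described without a test.

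The 16 gene lists were X multicopy, X single-copy, Y short arm, Y long arm, meiotic prophase, spermatid, spermatogonia, Sertoli, Leydig, peritubular and blood, histone clusters, histone H3.3, imprinted, housekeeping, olfactory receptors and vomeronasal receptors. The windows overlapping their genes were tested with camera (limma 3.58.1) with an estimated correlation, adjusted over the 16 lists; a preset correlation of 0.01 and fry were alternatives. Windows of each list that passed were counted both with the adjustment over all windows and with p-values adjusted over the list alone. The H3.3 calls of the Sertoli list against Cg are not reported here. The rank correlation of enrichment with the number of genes per window was computed per library.

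Named windows followed this rule: called windows of one direction next to each other, or with 1 window between, were merged; the 10 regions with the smallest adjusted p per direction were taken, at most 3 per chromosome, those with a protein-coding gene first, changed the same way in every pair of libraries; windows with pooled input over 5 times or under 0.2 times the median (1505 of 54520) were left out. Up to 2 genes of the top window, up to 4 members per list with the smallest p, and chromosomes X, Y, 8, 12, 1, 3, 9 and 14 were named. A window names the gene it overlaps; at 50 kb, signal cannot be assigned to a promoter or gene body, and reads from near-identical copies on X, Y and in gene families cannot be told apart.

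Alternatives tried were DESeq2 1.42.0 with its own size factors (mean dispersion fit for γH2AX windows, gene-wise dispersions for the 21 chromosome sums), library totals without TMM, TMM on 12 autosomes in no translocation (without 7, which differs in the B6.SPRET7MOLF12 parent), a minimum mean count of 50 or of 1 count in all, a replicate block, windows of 250 kb, X and Y left out, chromosomes 7 and 12 left out, an adjusted p under 0.01 for shared calls, windows of unusual input left out, a proximal region of 3 to 8 Mb, another enrichment reference, a median of windows, and each replicate left out in turn. Leaving out 1Rb_M replicates 1 and 2, and a covariate for the coefficient of variation (CV) of counts over windows, were added after the data were seen, as was an added count of 5 in place of 0.5. A correction for GC content needs the genome sequence and was not run.

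On simulated counts for the H3.3 comparison of 1Rb with Cg (53117 windows, 50 changed per size), 10% of windows changed 1.1-fold and 100% of those changed 1.25-fold or more were recovered, with 14 false calls of 169. For γH2AX 3Rb against 1Rb_M (53118 windows), 4%, 78%, 96% and 100% were recovered at 1.1-, 1.25-, 1.5- and 2-fold, with 8 false calls of 147. A list raised 1.15-fold gave a camera p of 1.96e-06 (H3.3) and 5.49e-05 (γH2AX), and 0 of 20 random lists had an unadjusted p under 0.05 in either. The simulated windows were drawn independently of each other. In the real lists the estimated correlation ran from 0.0115 to 0.657 for H3.3 and from −0.0186 to 0.993 for γH2AX. The power of camera on the real lists is therefore not shown. Figures were drawn with matplotlib 3.10.9; tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.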

Results

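The distribution of 2 chromatin marks was measured by ChIP-seq in whole testis of mice heterozygous for Robertsonian translocations, in which 2 chromosomes are joined at their centromeres. The question set by the study's title is how such translocations alter where γH2AX and histone H3.3 lie in the germ cell genome. γH2AX was profiled at 4 weeks in 3 libraries each of 1Rb_M, 1Rb_P and 3Rb, and in 1 library of C57BL/6J (B6). 1Rb_M and 1Rb_P are reciprocal crosses carrying the translocation that joins 8 and 12, from the mother or from the father. 3Rb is a cross of B6.SPRET7MOLF12 with RBF/Dnj. H3.3 was profiled at 6 weeks in 3 libraries each of 1Rb (the 1Rb_M cross), 3Rb and Cg, the B6.SPRET7MOLF12 control without a translocation. Totals of γH2AX libraries were 45527545 to 56385465 counts in the carriers and 21535147 in B6. H3.3 libraries held 41278440 to 128348440 counts and the 3 inputs 11876426 to 51651953.

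Chromosomes X and Y, which form the γH2AX-coated sex body of pachytene spermatocytes, held the highest γH2AX enrichment of the 7 regions compared. X took 17.99 ± 0.386% of γH2AX counts in 1Rb_P (SD, n = 3), 18.5 ± 0.546% in 3Rb and 14.5 ± 3.77% in 1Rb_M, against 3.16 to 3.17% in the inputs. Relative to input and to the autosomes in no translocation, X was enriched 7.36-fold in 1Rb_P, 7.69-fold in 3Rb and 5.44-fold in 1Rb_M. The wide spread in 1Rb_M came from replicates 1 and 2, with 12.3% each on X against 18.9% in replicate 3. Y took 8.55 ± 0.355% of γH2AX counts in 1Rb_P, 7.22 ± 0.258% in 3Rb and 7.06 ± 1.65% in 1Rb_M, against 1.66 to 1.74% in the inputs. H3.3 was also enriched on both: X held 6.18 ± 0.153% of counts in Cg and Y held 3.32 ± 0.108% (SD, n = 3).

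Next to the centromeres of 8 and 12, the pair joined in every carrier, γH2AX was enriched in all 9 carrier libraries. Their proximal 10 Mb stood above that of the other autosomes by a mean log2 ratio of 0.68 ± 0.16, or 1.60-fold (SD, n = 9 libraries; exact sign-flip p = 0.00391). In the B6 library, without a translocation, the same log2 ratio was −0.16. For the proximal 10 Mb of 1, 3, 9 and 14 the mean log2 ratio was −0.36, with 0 of 9 carrier libraries above 0 (exact sign-flip p = 0.00391). It was −0.48 in 1Rb, where these chromosomes are free. Without windows of unusual input the mean over the 9 libraries was 0.01, with 3 above 0 (exact sign-flip p = 0.906). That of the 6 1Rb libraries was then −0.17, with 0 above 0. The low mean over all carriers thus depended on these windows. For 8 and 12 the mean without them was 0.84, with 9 of 9 above 0. The sign-flip test thus also responds to differences between regions without a translocation. The group means of enrichment in the proximal 10 Mb of 8 and 12 were 0.70 ± 0.29 in 1Rb_M, 0.84 ± 0.02 in 1Rb_P and 0.69 ± 0.03 in 3Rb on the log2 scale (SD, n = 3), against −0.10 in B6. By chromosome, the median proximal window stood at a log2 of 0.91 ± 0.02 on 8 and 1.05 ± 0.03 on 12 in 1Rb_P, and at −0.14 and 0.06 in B6. All 9 carrier libraries lay above B6 in every 1 Mb bin from 3 to 21 Mb of chromosome 8 and from 3 to 22 Mb of chromosome 12. Chance gives this in 10% of bins. Over whole chromosomes such bins made up 55.9% of 8 and 39.8% of 12, and from 5.37% (5) to 50.8% (19) of the other autosomes, where the longest run was of 11 Mb (23 to 34 Mb of 9). B6 lay above all carriers on X (log2 3.16, carriers 2.18 to 2.98) and on Y (3.14, carriers 2.05 to 2.78), and below them in the rest of 8 and 12 (0.03, carriers 0.06 to 0.15). B6 is 1 library with another antibody supplier label, so no test between B6 and carriers was run.

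**Figure D1:**
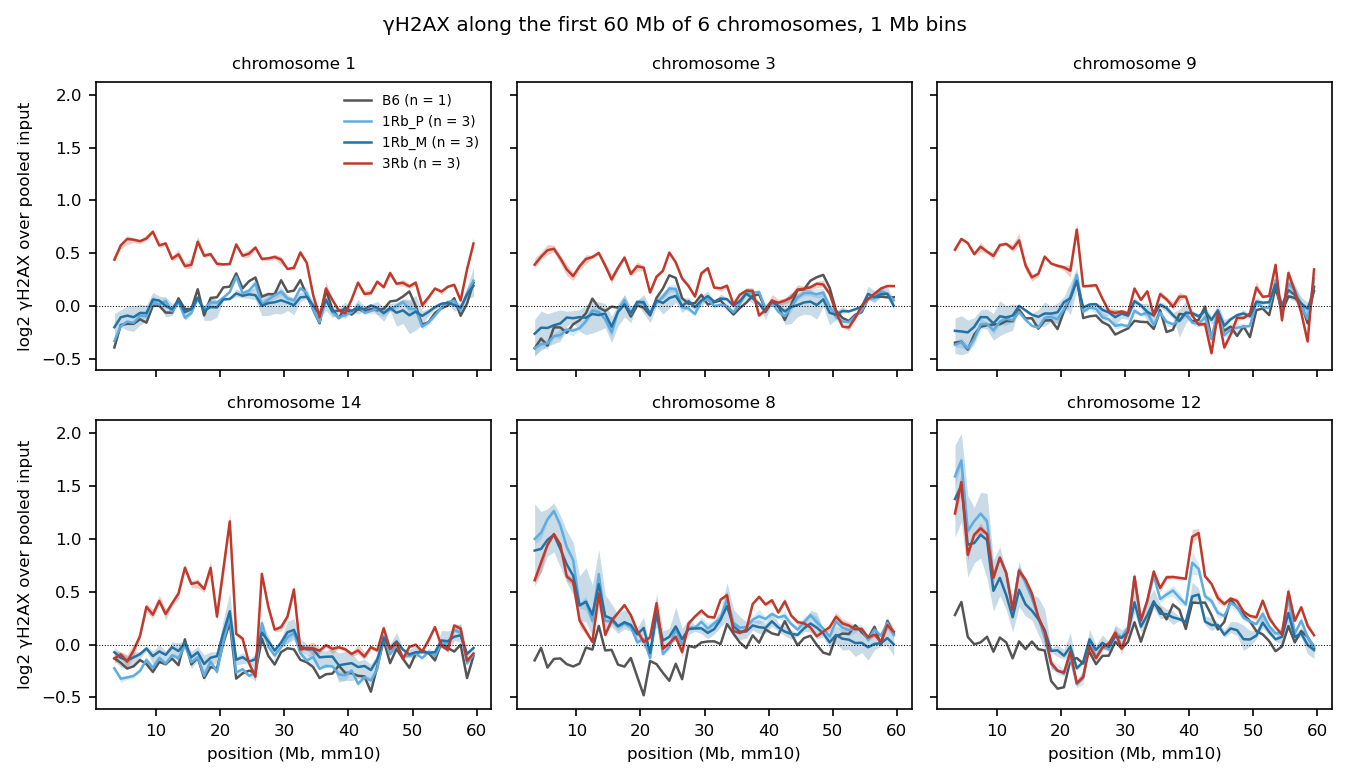
γH2AX as log2 ratio to pooled input (vertical axis) in 1 Mb bins along the first 60 Mb of 6 chromosomes (horizontal axis, position in Mb); lines are group means, shading the range over 3 libraries, and B6 is 1 library. On 8 and 12 all carriers lie above B6 next to the centromere. On 1, 3 and 9, 3Rb lies above both 1Rb crosses next to the centromere. On 14 the median log2 difference from 1Rb_M is −0.01 at 3 to 8 Mb and 0.39 at 8 to 13 Mb.

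**Figure D2:**
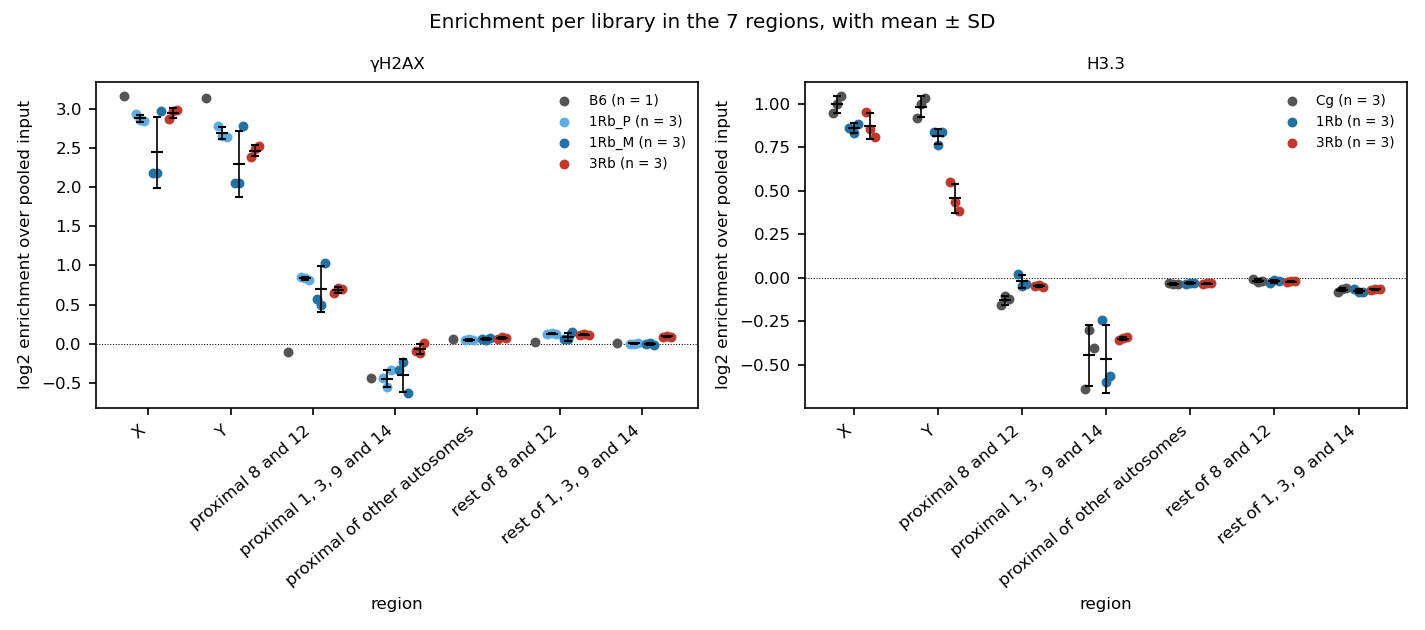
Log2 enrichment over pooled input (vertical axis) in the 7 regions (horizontal axis) for γH2AX and H3.3; points are libraries, bars mean and SD per group. The proximal 10 Mb of 8 and 12 has a γH2AX mean of 0.69 to 0.84 in the carrier groups and −0.10 in B6.

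Chromosomes 1, 3, 9 and 14, joined in 3Rb and free in 1Rb, gained γH2AX over their proximal 10 Mb in 3Rb relative to 1Rb. Of the 800 windows in their proximal 10 Mb, 711 rose and 8 fell against 1Rb_M, and 737 rose and 1 fell against 1Rb_P, with median log2 differences of 0.55 and 0.63 (edgeR, adjusted over all windows, n = 3 per group). The median proximal window stood at a log2 enrichment of 0.59 ± 0.02 on chromosome 1 in 3Rb against −0.06 ± 0.08 in 1Rb_M, −0.10 ± 0.02 in 1Rb_P and −0.10 in B6. On 3 it stood at 0.43 ± 0.03 in 3Rb and −0.24 ± 0.02 in 1Rb_P, on 9 at 0.55 ± 0.01 and −0.22 ± 0.03, and on 14 at 0.18 ± 0.03 and −0.22 ± 0.01 (SD, n = 3). Pooled over the 4, the difference from 1Rb_P had a median log2 of 0.73 at 3 to 8 Mb, 0.57 at 8 to 13 Mb, 0.45 at 13 to 23 Mb, 0.23 at 23 to 33 Mb and 0.11 at 33 to 43 Mb. It shrank over these bands on 1, 3 and 9, whereas on 14 it rose from 0.16 at 3 to 8 Mb to 0.70 at 13 to 23 Mb and then fell. Against 1Rb_M, 14 showed no gain at 3 to 8 Mb (median log2 −0.01) and stood at 0.39 at 8 to 13 Mb. All 3Rb libraries lay above all 6 1Rb libraries from 3 to 35 Mb of chromosome 1, 3 to 34 Mb of 3 and 3 to 27 Mb of 9. On 14 the longest such run was from 79 to 98 Mb, and 58.2% of its bins were so placed, where chance gives 1.19%. Such bins were not particular to the joined chromosomes: the autosomes in no translocation had 5.59% (7) to 40.7% (13), and 1, 3 and 9 had 30.6 to 38.2%. For the region as a whole the log2 difference of 3Rb from both 1Rb crosses was 0.36, or 1.28-fold (exact permutation p = 0.0238, the smallest the design allows; adjusted p = 0.0833). Without windows of unusual input it was 1.51-fold. Within the 3Rb libraries, this region lay below the proximal region of the other autosomes by a log2 of −0.14 with all windows (0 of 3 libraries above) and above it by 0.39 without windows of unusual input (3 of 3), so its level beside other centromeres depended on these windows. The rest of 1, 3, 9 and 14 was higher by a log2 of 0.09 in 3Rb (exact permutation p = 0.0238, adjusted p = 0.0833). The proximal 10 Mb of 8 and 12 had a log2 difference of −0.08 between 3Rb and 1Rb (exact permutation p = 0.548), X of 0.28 (exact permutation p = 0.119) and Y of −0.03 (exact permutation p = 0.952).

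Across the genome, 20396 of 53118 windows (38.4%) differed in γH2AX between 3Rb and 1Rb_M, 9649 higher and 10747 lower in 3Rb (edgeR, n = 3 per group). Between 3Rb and 1Rb_P 12315 differed (23.2%), 5465 higher and 6850 lower. The median size was 0.26 log2 units in each. DESeq2 called 7237 higher and 7732 lower against 1Rb_M, and 3166 higher and 3870 lower against 1Rb_P. Of whole chromosomes, 1, 3, 13 and 14 rose in 3Rb against both crosses. Chromosome 14 rose by a log2 of 0.19 ± 0.025 (SE; adjusted p = 0.000943 against 1Rb_M and 0.00229 against 1Rb_P), and 1 by 0.085 ± 0.023 and 0.10 ± 0.023 (adjusted p = 0.0214 and 0.0125). Chromosomes 5, 11 and 17 fell against both, 11 by a log2 of −0.086 and −0.066 (adjusted p = 0.00121 and 0.00888). Chromosomes 4 and 7 fell against 1Rb_M alone and 16 against 1Rb_P alone. The difference between these contrasts was not tested per chromosome. Chromosome 9 stood at 0.18 ± 0.065 against 1Rb_P (adjusted p = 0.0605), 8 at −0.06 (adjusted p = 0.0958), and 12 at −0.02 (adjusted p = 0.589). X stood at 0.06 ± 0.19 (adjusted p = 0.845) and Y at −0.23 ± 0.17 (adjusted p = 0.342). Against 1Rb_M, 9 stood at 0.13 (adjusted p = 0.132), X at 0.44 ± 0.19 (adjusted p = 0.106) and Y at 0.12 (adjusted p = 0.636). The sum of 9 includes the window at 3000001, with 2.20 to 2.70% of all counts in 1Rb_P and 2.71 to 3.08% in 3Rb. The median window of 9 changed by a log2 of 0.036 against 1Rb_P and 0.020 against 1Rb_M. With library totals in place of TMM the split against 1Rb_M moved to 4531 higher and 16197 lower, and no chromosome was called against 1Rb_P. It also turned the direction against 1Rb_M on 1 (−0.016), 3 (−0.0094) and 13 (−0.043). With a replicate block 4 and 13 lost their calls against 1Rb_M, which left 7, and 3, 5, 13 and 17 against 1Rb_P, which left 4; 1, 11 and 14 remained called against both. Without 1Rb_P replicate 1, 8148 windows and 3 chromosomes were called against 1Rb_P. The chromosomes called against it were 3 to 4 without any 1 of the 3Rb replicates and 14 without 1Rb_M replicate 3. Against 1Rb_M, 5 chromosomes were called without 3Rb replicate 1.

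Rankings by adjusted p in this paragraph hold among the windows that the naming rule allows. The gain with the smallest adjusted p against both crosses lay at Snrpn and Snurf. This is the imprinted pair of the Prader-Willi region on chromosome 7 (59950001 to 60000000). The window had 35.3 ± 2.69 CPM in 3Rb against 11.1 ± 0.828 in 1Rb_M and 10.7 ± 0.496 in 1Rb_P. Its log2 differences were 1.67 ± 0.07 (SE; adjusted p = 1.9e-19) and 1.71 ± 0.08 (adjusted p = 2.1e-19). Next to the centromere of 9, a run of called windows from 3050001 to 20650000 had its smallest adjusted p at Cwf19l2, with 24.8 ± 0.375 CPM against 11.8 ± 1.148 in 1Rb_M (log2 1.07 ± 0.06, adjusted p = 1.0e-16). On chromosome 1 the window with the smallest adjusted p was at Rb1cc1, which encodes an autophagy protein, against 1Rb_M (log2 1.01, adjusted p = 1.5e-15), and at Tcea1, a transcription elongation factor gene, against 1Rb_P (log2 1.11). On 14 such windows lay at Ube2e2, a ubiquitin-conjugating enzyme gene (log2 1.04 and 1.09), and at Ppp3cb and Usp54 (0.97 and 1.09). On 3 the window lay at Zc2hc1a (0.91 and 1.06). Outside the joined chromosomes, Naip6, an innate immune receptor gene on 13, rose by a log2 of 1.36 and 1.27, LOC115490339 on 6 by 1.17 and 1.33, and BC035044 with Clec2i on 6 by 0.83 and 0.94. Gm20830 on Y rose by 3.51 ± 0.27 against 1Rb_M, from 35.8 to 410 CPM, and Fbxw23 on 9 by 0.77 against 1Rb_P. γH2AX was lower in 3Rb than in both crosses at H60b, a ligand gene of the NKG2D receptor (log2 −1.05 and −1.01), and at the major urinary protein genes Mup1 (−0.98 and −0.82) and Mup17 (−1.25 and −1.12). Losses against both also lay at H2-D1 of the major histocompatibility complex with Ddx39b (−0.91 and −0.82) and at Glp1r (−0.81 and −0.71). The synaptic adhesion gene Nlgn1 was lower by −0.96 and −1.154, and Gm51571 with Gm51572 on 8 by −0.72 and −0.59. Among the 10 losses named by adjusted p against 1Rb_M, but not against 1Rb_P, were the neuronal splicing factor gene Rbfox3 (−0.82), Ift27 with Pvalb (−0.70) and the glutamate receptor gene Grm4 (−0.70). Among those against 1Rb_P, but not against 1Rb_M, were the chemokine gene Ccl21b (−1.30), the Snrpn window at 60450001 (−0.69) and the collagen gene Col23a1 (−0.60). Naip6, LOC115490339, BC035044, Fbxw23, Gm20830, H60b, Mup1, Mup17 and Snrpn at 60450001 were also named, in the same direction, for H3.3 between 3Rb and 1Rb. In 72 windows off the Y with large H3.3 differences, γH2AX against 1Rb_M changed the same way in 100%, with a median ratio of 1.251. At such windows strain copy number or read mapping was not separated from a change of γH2AX itself. The window at Snrpn and Snurf was not among those named for H3.3, but there too these were not separated, since no 3Rb input was used.

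Among the gene lists, those on autosomes held more losses than gains in 3Rb against 1Rb_M, except olfactory receptors, with 90 of 617 windows higher and 49 lower (80 and 42 adjusted over the list alone). Over all 53118 windows 9649 were higher and 10747 lower, a larger share in both directions than in olfactory receptors. In the autosomes of no translocation, 51.0% of windows with 3 or more genes and 27.4% of those with 1 to 2 genes were lower. Losses in the lists below are therefore not shown to be particular to their genes. Of 24 spermatid windows 12 were lower and 0 higher over all windows, and 13 and 0 adjusted over the list alone. They were led by Gapdhs, the sperm glycolytic enzyme gene (log2 −0.38), the sperm-egg fusion gene Izumo1 (−0.41) and the protamine gene Prm1 (−0.34). Camera with an estimated correlation gave this list p = 0.0298, adjusted p = 0.477. The histone clusters list, which also took linker histone genes outside the clusters, had 10 of 19 windows lower and 0 higher (11 and 0 adjusted over the list alone; camera adjusted p = 0.524), with 2 of these, H1f8 (−0.52) and H1f0 (−0.38), first. Imprinted genes had 5 higher and 22 lower of 54 (6 and 23 adjusted over the list alone), with Rasgrf1 at −0.39 beside the gain at Snrpn. The meiotic prophase list was mixed, 13 higher and 15 lower of 70 (14 and 16 adjusted over the list alone), with the recombination genes Msh5 (−0.51) and Dmc1 (−0.35) among the losses. Spermatogonia had 9 of 23 lower (9 adjusted over the list alone). Sertoli had 4 higher and 8 lower of 21 (5 and 8), with Cldn11 at 0.52 and Amh at −0.41. Leydig had 4 of 10 lower, with Cyp11a1 at −0.39, peritubular and blood 4 of 12 lower, and housekeeping 1 higher and 6 lower of 16. Of the 2 windows of H3.3 genes, H3f3b was lower (−0.19, adjusted p = 0.011). X multicopy genes had 11 of 76 windows higher (4 adjusted over the list alone), led by the spermatid-expressed Srsx (2.84) and by Ott (1.60), and X single-copy genes 6 of 49 (0 adjusted over the list alone). Of all X windows 21.9% were higher, a larger share than in either list. The Y short arm had 0 higher and 1 lower of 19 (Rbmy, −0.83), the Y long arm 2 higher and 2 lower of 5, and vomeronasal receptors 42 higher and 61 lower of 489 (23 and 50 adjusted over the list alone). Camera with an estimated correlation called 0 of the 16 lists, with 1 at an unadjusted p under 0.05. With the preset correlation 8 passed and fry passed 5.

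Against 1Rb_P calls were fewer in each list except the Y short arm, with more, and Leydig, housekeeping and H3.3 genes, with as many. Over all 53118 windows 5465 were higher and 6850 lower. In the autosomes of no translocation, 40.6% of windows with 3 or more genes and 16.4% of those with 1 to 2 genes were lower. Spermatid windows had 1 higher and 9 lower (1 and 10 adjusted over the list alone; camera adjusted p = 0.882 with an estimated correlation), with Gapdhs at −0.36 and Prm1 at −0.34, and Acrv1, an acrosomal protein gene on 9, at 0.23. Meiotic prophase had 4 higher and 10 lower, and imprinted 5 and 6 (5 and 5 adjusted over the list alone). Histone clusters had 0 and 4, Leydig 0 and 4, peritubular and blood 0 and 3, housekeeping 1 and 6, Sertoli 2 and 1 and spermatogonia 0 and 1 (0 and 0 adjusted over the list alone). Olfactory receptors had 78 higher and 15 lower (72 and 15 adjusted over the list alone) and vomeronasal receptors 49 and 32 (35 and 24). X multicopy had 1 and 0 (Srsx, 1.40) and X single-copy 0 and 0 (edgeR, with 0 at an unadjusted p under 0.05 and 0 by DESeq2). The Y short arm had 1 and 2 (Uty 0.69, Usp9y −0.67 and Rbmy −1.09) and the Y long arm 0 and 2 (2 and 2 adjusted over the list alone). Of the 2 H3.3 gene windows H3f3b was again lower (−0.17, adjusted p = 0.0315). Camera with an estimated correlation called 0 lists, with 0 at an unadjusted p under 0.05, against 4 with the preset correlation and 1 with fry.

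In the autosomes of no translocation, γH2AX losses in 3Rb were most frequent in gene-rich windows. Of 2012 windows with 3 or more genes, 51.0% were lower than in 1Rb_M and 40.6% lower than in 1Rb_P, against 15.4% and 6.91% of 12396 windows with no gene. Windows are not independent replicates. Per library, over all autosomes, the rank correlation of γH2AX enrichment with gene number was −0.13 ± 0.03 in 3Rb (SD, n = 3) and 0.01 ± 0.14 in the 6 1Rb libraries, a difference within the spread (exact permutation p = 0.143). All 3Rb libraries lay below all of 1Rb_P (exact permutation p = 0.1, the smallest 3 against 3 allow), and 1Rb_M replicate 2, at −0.191, lay below all 3Rb libraries (3Rb against 1Rb_M, exact permutation p = 0.4). For H3.3 the correlation was 0.572 ± 0.0041 in the 6 carrier libraries and 0.572 ± 0.0056 in Cg, so H3.3 was higher in gene-rich windows in every group (exact permutation p = 0.833 for the difference).

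The reciprocal 1Rb crosses, which ask whether the parent that transmits the translocation of 8 and 12 matters, differed in 880 windows (174 higher and 706 lower in 1Rb_M; 1.66%; edgeR, n = 3 per group). In the proximal 10 Mb of 8 and 12, 0 of 400 windows were called by edgeR, with 26 at an unadjusted p under 0.05 and 1 called by DESeq2, and the exact permutation p for the region was 0.4. The losses in 1Rb_M with the largest log2 differences among the named windows lay on X, where the crosses differ in their mothers' strain. The vomeronasal receptor gene Vmn2r121, in a run from 123050001 to 124700000, stood at 10.2 CPM against 53.2 (log2 −2.38 ± 0.20, SE; adjusted p = 4.3e-10). Gm15114, in a run from 147800001 to 150100000, fell by 1.66 ± 0.22 on the log2 scale. In these parts of X the input titled 1Rb_M also lay below both other inputs, by a log2 of −0.60 at 123 to 124 Mb, −0.65 at 124 to 125 Mb, −0.73 at 148 to 149 Mb and −0.81 at 149 to 150 Mb. Cphx1 with Tmem254a on 14 was lower by a log2 of −0.88, Gm10591 by −0.54 and Gm16867 by −0.53. Dach1 was lower by −0.36, Dgkb by −0.35, the adhesion gene Cadm2 by −0.33 and the axon guidance receptor gene Robo2 by −0.32. Gains in 1Rb_M were led by the TNF receptor family genes Tnfrsf26 and Tnfrsf22 (log2 0.85 ± 0.07, adjusted p = 3.0e-10; 21.7 against 12.03 CPM) and Lrmda (0.46 and 0.36 in neighbouring runs). Smaller ones were at Pkp3 with B4galnt4 (0.31), Mthfd1l (0.29), Ear1 and Phrf1 (0.28 each), and Tnik, Gm3993 and Pramel44 (0.26 each). Of the lists, X multicopy had 4 windows lower (Ott −1.55, Srsx −1.44) and meiotic prophase 3 lower (3 higher and 4 lower adjusted over the list alone; Mei4, a recombination gene, −0.27). Vomeronasal receptors had 2 lower and olfactory receptors 1 higher and 2 lower (0 adjusted over the list alone). Imprinted and spermatogonia windows had 2 higher each and Leydig 1 adjusted over the list alone, and 0 over all windows by edgeR, with 10, 6 and 2 at an unadjusted p under 0.05 and 0 by DESeq2. The other 9 lists had 0 calls by edgeR, with at most 8 windows (Sertoli) at an unadjusted p under 0.05, and DESeq2 called 1 each in Sertoli and X single-copy. Camera with an estimated correlation called 0 of 16, with imprinted genes at p = 0.0472 and adjusted p = 0.504, against 9 with the preset correlation and 0 with fry. By edgeR 0 chromosomes were called, with 4 at an unadjusted p under 0.05 and 5 called by DESeq2. X stood at −0.38 ± 0.19 and Y at −0.35 (adjusted p = 0.296 each), 12 at −0.07 (adjusted p = 0.19). The count and its direction depended on the scaling and on single libraries. Library totals without TMM gave 414 higher and 176 lower, and DESeq2 20 and 468. The count was 160, 5787 and 13430 without 1Rb_M replicates 1, 2 and 3, 488, 264 and 185 without 1Rb_P replicates 1, 2 and 3, and 568 without 3Rb replicate 3.

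H3.3 was compared between carriers and Cg to ask where the variant is gained or lost with a translocation. Next to the centromeres of 8 and 12, 153 of 400 windows rose and 0 fell in 1Rb, and 126 rose and 1 fell in 3Rb (edgeR, n = 3 per group; median log2 differences 0.12 and 0.10). The median proximal window of 8 moved from a log2 enrichment of −0.25 ± 0.01 in Cg to −0.07 ± 0.04 in 1Rb and −0.13 ± 0.02 in 3Rb, and that of 12 from −0.27 ± 0.01 to −0.13 ± 0.03 and −0.18 ± 0.02 (SD, n = 3). In 1Rb the difference on 8 and 12 was 0.26 at 3 to 8 Mb, 0.07 at 8 to 13 Mb and 0.03 at 13 to 23 Mb. For the region as a whole, all 6 carrier libraries lay above all 3 of Cg, by a log2 of 0.09 (exact permutation p = 0.0238, adjusted p = 0.0833). Cg, from B6.SPRET7MOLF12, differs from both carrier crosses in parental strains. Strain and translocation were therefore not separated in these H3.3 differences on 8 and 12. In the proximal 10 Mb of 1, 3, 9 and 14, 151 windows rose and 60 fell in 3Rb, and 3 rose and 4 fell in 1Rb. Between 3Rb and 1Rb directly 87 rose and 49 fell. The median proximal window of 9 stood at −0.32 in 3Rb, −0.48 in 1Rb and −0.47 in Cg, that of 1 at −0.35, −0.46 and −0.45, that of 3 at −0.36, −0.48 and −0.49, and that of 14 at −0.32, −0.24 and −0.24. On 14 the direction depended on the summary: the median change of single windows in 3Rb was 0.018 against Cg and −0.019 against 1Rb, with −0.16 at 3 to 8 Mb and 0.10 at 8 to 13 Mb against Cg. The exact permutation p for this region was 0.667 for carriers against Cg. This pools 3Rb with 1Rb, where these chromosomes are free, so it does not test a change in 3Rb alone.

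**Figure D3:**
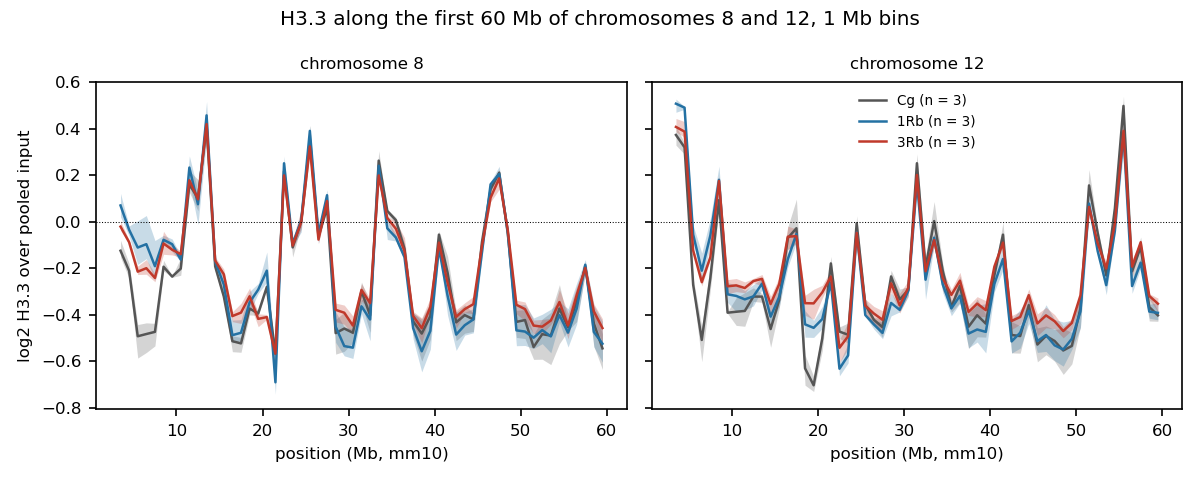
H3.3 as log2 ratio to pooled input (vertical axis) in 1 Mb bins along the first 60 Mb of 8 and 12 (horizontal axis, position in Mb); lines are group means and shading the range over 3 libraries. Both carrier groups lie above Cg next to the centromere.

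Windows of the sex chromosomes lost H3.3 in carriers. Of 3310 windows on X, 573 fell and 97 rose in 1Rb and 896 fell and 48 rose in 3Rb. Of 1790 on Y, 361 fell and 1 rose in 1Rb and 1534 fell and 201 rose in 3Rb. As a whole, Y fell by 30.3% in 3Rb (log2 −0.52 ± 0.048, SE; adjusted p = 0.000268), while in 1Rb it stood at −0.16 ± 0.048 (adjusted p = 0.0761). X stood at −0.13 ± 0.039 in 1Rb (adjusted p = 0.0761) and at −0.12 ± 0.039 in 3Rb (adjusted p = 0.0744). The share of H3.3 counts on Y was 3.32 ± 0.108% in Cg, 2.98 ± 0.0770% in 1Rb and 2.33 ± 0.131% in 3Rb. Between 3Rb and 1Rb, Y fell by 22.1% (log2 −0.36 ± 0.048, adjusted p = 0.00294), with X at 0.01 (adjusted p = 0.793). In the enrichment over input, carriers stood below Cg by a log2 of −0.35 on Y (exact permutation p = 0.0238, adjusted p = 0.0833) and −0.13 on X (exact permutation p = 0.0476, adjusted p = 0.111). The 3Rb Y comes from RBF/Dnj, whereas the Y of Cg and of 1Rb comes from B6.SPRET7MOLF12, so strain and translocation cannot be separated on Y. The X of 1Rb comes from the mother that transmits the translocation, and the X of Cg from B6.SPRET7MOLF12. Strain and translocation therefore cannot be separated on X in 1Rb either. In parts of X (123 to 126 and 148 to 150 Mb) the input titled 1Rb_M also lay below both other inputs.

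**Figure D4:**
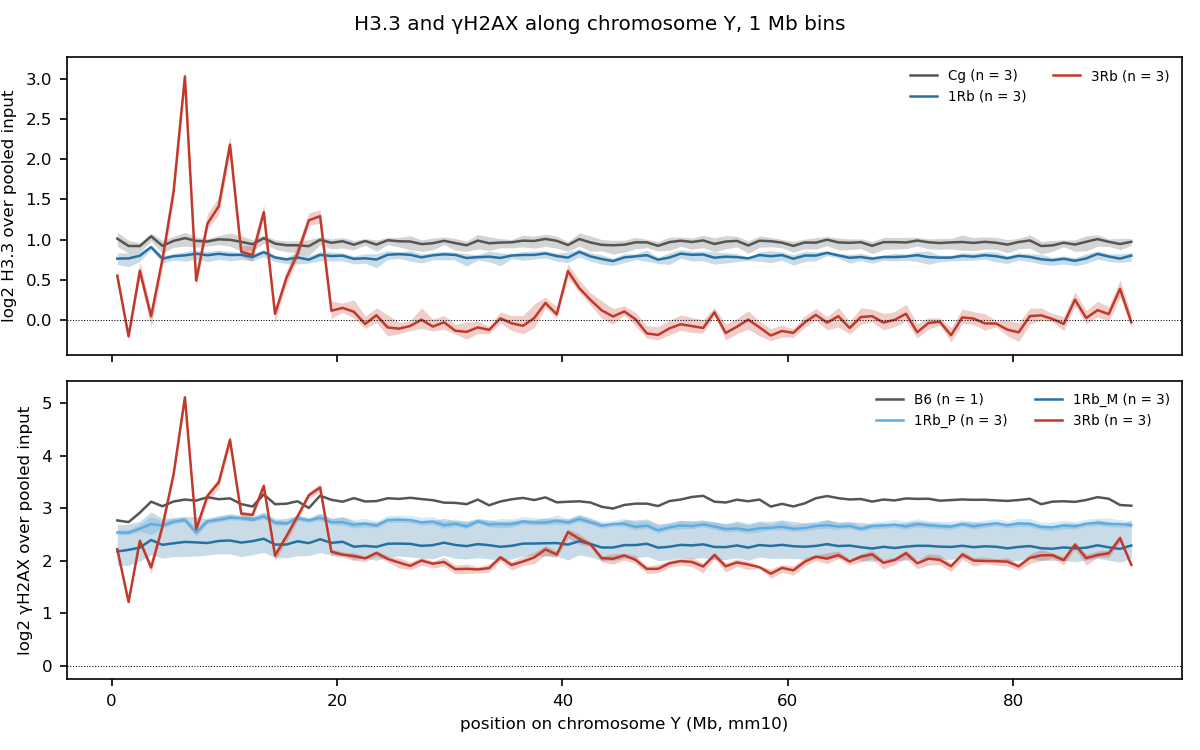
H3.3 and γH2AX as log2 ratio to pooled input (vertical axis) in 1 Mb bins along Y (horizontal axis, position in Mb); lines are group means and shading the range over 3 libraries. 3Rb differs from the other groups in both directions along the chromosome, with a gain at Gm20830 and a loss around Gm21076.

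Over all windows, 2042 of 53117 (3.84%) differed in H3.3 between 1Rb and Cg, 587 higher and 1455 lower (edgeR, n = 3 per group). Between 3Rb and Cg 5064 differed (1730 and 3334; 9.53%) and between 3Rb and 1Rb 3225 (1096 and 2129; 6.07%). Median sizes were 0.25, 0.26 and 0.55 log2 units. DESeq2 gave 485 higher and 922 lower, 1267 and 2689, and 939 and 2061. Among autosomes, 12 rose by a log2 of 0.014 ± 0.0029 in 1Rb (adjusted p = 0.0343) and 0.018 in 3Rb (adjusted p = 0.00498), and 16 by 0.014 in 3Rb (adjusted p = 0.0172). Chromosome 8 stood at 0.02 in 1Rb (adjusted p = 0.38). Parental strain was not separated from the translocations in these comparisons with Cg. Both autosomal calls in 3Rb were lost with library totals, with TMM on 12 autosomes, where 16 turned to −0.0015, and with a replicate block. The call on 12 in 3Rb was lost without windows of unusual input, 1Rb replicates 2 or 3, Cg replicate 1 or 3Rb replicate 1, and that on 16 without any 1 library except 1Rb replicate 1. The call on 12 in 1Rb was lost with DESeq2, library totals, TMM on 12 autosomes, a replicate block, without windows of unusual input, and without any 1 of the 1Rb or 3Rb replicates or Cg replicates 2 or 3, and 7 chromosomes were called without Cg replicate 1. The count for 1Rb against Cg was 4335 without Cg replicate 1 and 1216 without 1Rb replicate 2. The count for 3Rb against Cg was 3221 and 3257 without 3Rb replicates 2 and 3, and library totals without TMM gave it 2463 higher and 2998 lower. That for 3Rb against 1Rb was 4942 without 1Rb replicate 1.

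**Figure D5:**
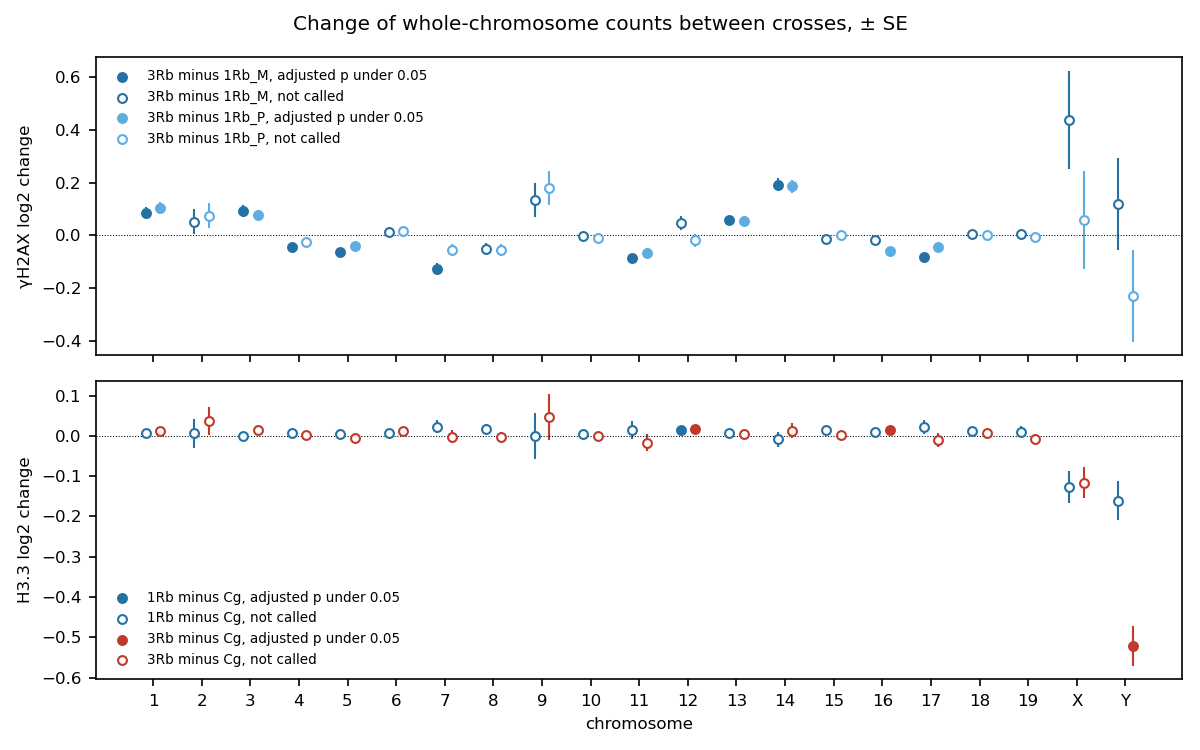
Log2 change per chromosome with its SE (vertical axis) for 21 chromosomes (horizontal axis), for γH2AX in 3Rb against each 1Rb cross and for H3.3 in 1Rb and 3Rb against Cg; filled points have an edgeR adjusted p under 0.05. Y has the largest H3.3 change, a log2 of −0.52 in 3Rb.

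Single windows named for H3.3 lay on X, on Y and on autosomes. In 1Rb against Cg, Vmn2r121 on X fell from 20.9 ± 1.84 to 7.94 ± 0.371 CPM (log2 −1.38 ± 0.06, SE; adjusted p = 9.9e-20) and Ott on X by 1.33 ± 0.06 on the log2 scale (adjusted p = 3.5e-19). The input titled 1Rb_M lay below both other inputs in the bins that hold them, by a log2 of −0.65 at 124 to 125 Mb and −0.81 at 149 to 150 Mb. Lower as well were 9230019H11Rik (−0.96), Gm1993 on X (−0.84) and Gm6605 (−0.75). Further losses were at Zfp781, Sprr2a1 of the cornified envelope cluster and the olfactory receptor pair Olfr1432 and Olfr1431 (−0.72 each), and at Pla2g5 with Otud3 (−0.71) and Gm9271 (−0.65). Higher were Snrpn at 60450001 of chromosome 7 (log2 0.76 ± 0.05, adjusted p = 1.5e-14; 20.99 against 12.5 CPM), 2410141K09Rik (0.76), Zfp932 (0.95) and 1600014C10Rik (0.89). Other gains were at Vmn2r50 (0.82), 4933430I17Rik with Alad (0.72), Kctd16 (0.67), Naip1 (0.65), the immune receptor pair Cd244a and Ly9 (0.64) and Btbd35f23 on X (0.58). In 242 windows that differed by over 0.5 log2 units between 1Rb and Cg, the inputs differed the same way in 99.6%. The median ratio of the input difference to the H3.3 difference was 0.909. Strain copy number or read mapping was therefore not separated from a change of H3.3 itself at the windows named for 1Rb against Cg. In 3Rb against Cg, Gm20830 on Y rose by 2.86 ± 0.08 (adjusted p = 2.5e-27; 119 ± 7.54 against 16.5 CPM), and Gm21301 and Gm20918 on Y by 2.41 and 2.31. Cwc22 on 2, a splicing factor gene in a segment that varies in copy number among mouse strains, rose by 2.30 ± 0.07 (adjusted p = 3.5e-26; 105 ± 3.57 against 21.4 ± 0.759 CPM). Also higher were 1600014C10Rik (1.64), Srsx on X (1.34), Naip6 (1.28), LOC115490339 (1.101), Fbxw23 (0.89) and BC035044 with Clec2i (0.74). Among the windows that the naming rule allows, the loss with the smallest adjusted p lay on Y at Gm21076, in a run from 56700001 to 89350000 (log2 −1.98 ± 0.06, adjusted p = 3.1e-27). Gm21704 (−1.77) and Gm10352 (−1.70) on Y followed. Autosomal losses were at Nlgn1 (−0.89), Mup10 (−0.85), Gal3st2 with D2hgdh (−0.80), Mup17 (−0.72), Gm6605 (−0.71), H60b (−0.62) and Gm9271 (−0.61). The direct comparison of 3Rb with 1Rb named the same Y windows (Gm20830 2.99, Gm21301 2.59, Gm20918 2.42, Gm21076 −1.83, Gm21704 −1.64 and Gm10352 −1.56). Its other gains were at Srsx (2.58 ± 0.06), Cwc22 (2.34 ± 0.07), Naip6 (1.27), Ott (1.201), LOC115490339 (1.103), BC035044 (0.84) and Fbxw23 (0.79). Its other losses were at Mup17 (−1.11), H60b (−0.95), Mup1 (−0.88), Btbd35f23 and Gm46425 (−0.65 each), and Naip1 and Snrpn at 60450001 (−0.63 each).

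H3.3 losses on the sex chromosomes covered both single-copy and multicopy genes. Of all windows, 27.1% on X and 85.7% on Y were lower in 3Rb than in Cg, and 17.3% and 20.2% in 1Rb. In 3Rb against Cg, the Y short arm had 14 of 19 windows lower and 0 higher (16 and 0 adjusted over the list alone), led by the germ cell RNA-binding gene Rbmy (log2 −1.30), Usp9y (−0.62) and Uty (−0.46). The Y long arm, with multicopy genes expressed in spermatids, had 3 lower and 2 higher of 5. Sly fell by 1.46 and Ssty2 by 0.54, whereas Ssty1 (0.31) and Srsy (0.32) rose. X single-copy genes had 10 of 49 lower and 0 higher (29 and 0 adjusted over the list alone), such as Atp7a and Usp9x (−0.19 each). X multicopy genes had 20 of 76 lower and 1 higher (45 and 1 adjusted over the list alone; camera adjusted p = 0.730 with an estimated correlation). Srsx was the 1 higher, and Mageb1 at −0.26 was among the lower. In 1Rb against Cg these lists had no gains. The Y short arm had 2 of 19 lower (3 adjusted over the list alone; Zfy2 −0.22), the Y long arm 2 of 5 (4; Sly −0.21 and Ssty1 −0.19), X single-copy 2 of 49 (4; Pgk1 −0.19) and X multicopy 9 of 76 (16; camera adjusted p = 0.596). Imprinted genes had 3 windows higher and 0 lower in 1Rb and 1 higher in 3Rb, the last at Snrpn (0.78). Vomeronasal receptors had 42 higher and 26 lower in 1Rb (48 and 35 adjusted over the list alone) and 93 and 48 in 3Rb (146 and 55), and olfactory receptors 4 and 8 (2 and 6) and 32 and 11 (27 and 10). The meiotic prophase list had 1 call in each, lower at Sycp1, a synaptonemal complex gene (−0.19 in 1Rb and −0.17 in 3Rb). Spermatid and spermatogonia lists had 1 lower each in 3Rb, Spag6 at −0.16 and Uchl1 at −0.17, and 0 in 1Rb by edgeR or by DESeq2, with 0 at an unadjusted p under 0.05. Adjusted over the list alone, none of these remained. Leydig, peritubular and blood, histone clusters, histone H3.3 and housekeeping lists had 0 windows called by edgeR or by DESeq2 in either contrast, with 2 Leydig and 1 peritubular and blood window at an unadjusted p under 0.05 in 3Rb and 0 in 1Rb. Between 3Rb and 1Rb, X multicopy had 4 higher, the Y short arm 4 lower (7 adjusted over the list alone) and the Y long arm 2 higher and 3 lower. Imprinted had 1 higher and 2 lower, spermatogonia 1 lower (Zbtb16, −0.19), olfactory receptors 17 and 7 and vomeronasal receptors 37 and 41 (46 and 43). The other 9 lists had 0 calls there by edgeR and 0 by DESeq2, with at most 7 windows (meiotic prophase) at an unadjusted p under 0.05. Camera with an estimated correlation called 0 of 16 lists in each H3.3 contrast, with 0 at an unadjusted p under 0.05, against 6, 6 and 3 with the preset correlation and 0, 2 and 1 with fry.

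H3.3 changes were partly shared between the carrier groups. Against Cg, 298 windows rose in both 1Rb and 3Rb, of 587 and 1730, where independent lists give 19.1. In both, 845 fell, of 1455 and 3334, where independent lists give 91.3. On autosomes alone 296 rose and 285 fell in both, where independent lists give 15.1 and 9.81. On X and Y 560 fell in both, where independent lists give 445, and 2 rose, where they give 4.78. Of the calls in 1Rb, 58 gains fell in 3Rb and 88 losses rose. Of the shared gains, 114 lay in the proximal 10 Mb of 8 and 12. Both contrasts use the same 3 Cg libraries, so part of the excess may come from these shared controls. Both carrier groups also differ from Cg in parental strains. Strain differences in copy number or read mapping were not separated from a change of H3.3 in the shared calls. In 10 simulations of unchanged groups with shared controls at most 1 window was called per contrast and direction, so they do not show how far shared controls raise the overlap of calls. The log2 changes of the 2 contrasts had a mean correlation of 0.498 in the simulations against 0.313 observed, and a covariance of 0.00172 against 0.00709. The 3 controls cannot be divided between the contrasts.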

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

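The tests with a covariate for the strength of enrichment were set out before their results were seen; every other test in this part was chosen after the result it bears on had been seen.

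H3.3 on Y changed by a different amount in the 2 carrier groups: the log2 change against Cg in 3Rb minus that in 1Rb was −0.36 ± 0.048 (SE; edgeR adjusted p = 0.00294, n = 3 per group), lower in 3Rb. In the inputs, which were pooled for region enrichment, the library titled 1Rb_M stood below both other inputs by a log2 of −0.60 at 123 to 124 Mb of X, −0.65 at 124 to 125 Mb, −0.74 at 125 to 126 Mb, −0.73 at 148 to 149 Mb and −0.81 at 149 to 150 Mb. The B6 input stood above both others by 0.54 at 4 to 5 Mb of Y.

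The first pattern is the set of windows with large H3.3 differences, such as Srsx, Ott, Cwc22, Naip6, Gm20830 and Gm21076. Copy number or read mapping that differs between the parental strains may account for those that separate 1Rb from Cg: in 242 windows differing by over 0.5 log2 units, the input difference between 1Rb_M and Cg had the same sign in 99.6% and a median of 0.909 times the H3.3 difference. No 3Rb input was used here, so for 3Rb the other mark was the test. In 72 windows off the Y that differed by over 1 log2 unit between 3Rb and 1Rb, γH2AX differed the same way in 100%, with a median ratio of 1.251, and in 589 windows on the Y in 100%, with a median ratio of 0.623; both values leave strain copy number and a shared change of the 2 marks open. The design gives no 3Rb animals with another parent's Y, so translocation, strain and copy number cannot be told apart for the windows on Y that separate 3Rb from 1Rb. For those off the Y they were not told apart either, since no 3Rb input was used.

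The second pattern is the γH2AX gain in the proximal 10 Mb of 1, 3, 9 and 14 in 3Rb. Strain copy number would move H3.3 alike, but the median H3.3 change was 0.155 times that of γH2AX over the 800 windows (0.09 against 0.55 log2 units), which argues against it as the whole source. Libraries that differ in strength of enrichment are also argued against, since with the covariate the median difference from 1Rb_P was 0.69 against 0.63 without it, and from 1Rb_M 0.66 against 0.55. A few windows with most of the counts are argued against too: without windows of unusual input the log2 difference was 0.596 against 0.356 with them. GC content was not tested and the parental strains differ with the translocations, so joining of these chromosomes in 3Rb remains a candidate explanation and strain an open one.

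The third pattern is the lower γH2AX in gene-rich windows of the free autosomes in 3Rb. Strength of enrichment is argued against as the whole source, since with the covariate the rank correlation of the difference from 1Rb_P with gene number was −0.311 against −0.218 without it, and from 1Rb_M −0.333 against −0.231, over 31278 windows. A bias of library preparation was left open. For the log2 ratio of each input to the pooled 3 inputs, the rank correlation with gene number ranged over 0.355, from −0.161 to 0.193. Each input is part of that pool, and a range of single libraries is not comparable with a difference between group means. It therefore cannot be weighed against the 0.143 by which 3Rb and 1Rb differed. Per library the exact permutation p was 0.143 against both crosses, 0.4 against 1Rb_M and 0.1 against 1Rb_P, the smallest that 3 against 3 allow, with all 3Rb libraries below all of 1Rb_P and 1Rb_M replicate 2 (−0.191) below all of 3Rb. The pattern itself is therefore not established.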

How the results depend on the processing

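The covariate for the CV of counts over windows, the removal of 1Rb_M replicates 1 and 2 and the added count of 5 were chosen after the data were seen; the other alternatives were planned. Named windows kept direction and call in 1204 values under other settings and lost the call, in the same direction, in 2. With 1 library left out 1065 kept it and 15 lost it. These windows were picked for small p-values and separated libraries, which favoured this stability, so it does not extend to the other calls. Called chromosomes kept their call in 115 values under other settings and lost it in 30, and with 1 library left out 146 kept it and 52 lost it. At this depth and spread between replicates, 1.1-fold changes were recovered in 10% (H3.3) and 4% (γH2AX) of simulated windows; no simulation varied depth alone, and counting error at the median window was 2.22 to 7.02%. The cause of the differences given here was not tested, except that fewer windows were tested where chromosomes were left out or windows widened. The GC correction, and the replicate block with it, were not run, and the planned larger pseudocount did not apply to the window tests, which use counts. For the median proximal windows of 8, 12, 1, 3, 9 and 14, an added count of 5 in place of 0.5 moved the 36 medians of the replicated groups by at most 0.0085 log2 units, each by less than its SD, and the 6 of B6 by at most 0.024.

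Window counts moved by over 1.5 times as follows. Without X and Y they were 1022 (H3.3 1Rb against Cg), 1937 (3Rb against Cg), 1004 (3Rb against 1Rb) and 546 (γH2AX 1Rb_M against 1Rb_P). With 250 kb windows they were 651, 1428 and 693 for H3.3 in that order, and 5100 (3Rb against 1Rb_M), 3588 (3Rb against 1Rb_P) and 407 (1Rb_M against 1Rb_P) for γH2AX. For γH2AX 3Rb against 1Rb_P, DESeq2 called 7036 windows, the CV covariate 23055, and without 1Rb_M replicates 1 and 2 there were 19848; for 1Rb_M against 1Rb_P these were 488, 13952 and 8719.

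Chromosome counts were more fragile. For H3.3 1Rb against Cg (1 called), DESeq2 called 2, library totals without TMM 0, TMM on 12 autosomes 0, removal of unusual input 0 and the CV covariate 4. For H3.3 3Rb against Cg (3 called), DESeq2 called 5, library totals 1 and TMM on 12 autosomes 1. For γH2AX 3Rb against 1Rb_P (8 called), library totals called 0, the CV covariate 14 and removal of 1Rb_M replicates 1 and 2 14; for 1Rb_M against 1Rb_P (0 called by edgeR, 4 at an unadjusted p under 0.05) DESeq2, the covariate and that removal called 5 each. Directions reversed for H3.3 chromosome 16, 3Rb minus Cg, with TMM on 12 autosomes (−0.0015) and, with library totals, for γH2AX 3Rb against 1Rb_M on 1 (−0.016), 3 (−0.0094) and 13 (−0.043).

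Region differences that reversed were all small. For γH2AX these were the proximal region of other autosomes at 3 to 8 Mb (−0.0201) and with a median reference (−0.00965), and the rest of 8 and 12 with a median reference (−0.0191) and without 1Rb_M replicates 1 and 2 (−0.0175). For H3.3 they were the proximal region of other autosomes at 3 to 8 Mb (−0.00115) and with a median reference (−4.21e-05), and the rest of 1, 3, 9 and 14 with the median of windows (0.00534). Of the lists, camera with the preset correlation called 6, 6 and 3 (H3.3) and 8, 4 and 9 (γH2AX), and fry 0, 2 and 1 and 5, 1 and 0. At an adjusted p under 0.01, 285 windows fell in both carrier groups.

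With 1 library left out, window counts ran from 1216 to 4335 (H3.3 1Rb against Cg), 3221 to 6460 (3Rb against Cg), 2752 to 4942 (3Rb against 1Rb), 15203 to 24619 (γH2AX 3Rb against 1Rb_M), 8148 to 18313 (3Rb against 1Rb_P) and 160 to 13430 (1Rb_M against 1Rb_P). Chromosome counts ran, in that order, from 0 to 7, 1 to 3, 1 to 2, 5 to 12, 3 to 14 and 0 to 13. The γH2AX differences of 3Rb from 1Rb ran from 0.185 to 0.342 on X, −0.115 to 0.0311 on Y, −0.135 to −0.0288 in the proximal region of 8 and 12, 0.314 to 0.395 in that of 1, 3, 9 and 14, −0.00422 to 0.0138 in the rest of 8 and 12 and 0.0909 to 0.0961 in the rest of 1, 3, 9 and 14. The H3.3 differences of carriers from Cg ran from −0.153 to −0.106 on X, −0.390 to −0.299 on Y, 0.0808 to 0.106 in the proximal region of 8 and 12, −0.0589 (without Cg replicate 1) to 0.111 in that of 1, 3, 9 and 14 and −0.00882 to 0.000388 in the rest of 1, 3, 9 and 14.

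Replicate numbers do not pair the samples: correlations of same-number libraries ran from −0.587 to 0.227. With a block on replicate number 1560, 3928 and 2931 windows were called for H3.3 (1557, 3925 and 2930 also called without it, in the order above) and 19341, 11325 and 590 for γH2AX (19156, 11282 and 577); chromosomes called with the block were 0, 1, 1, 7, 4 and 0.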

Other observations

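The tests of explanations in this part, and the counts over other splits of the libraries, were all chosen after the results they bear on had been seen.

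Along chromosome 14 the γH2AX difference between 3Rb and 1Rb_P did not decline steadily from the centromere: its median log2 was 0.16 at 3 to 8 Mb, 0.49 at 8 to 13 Mb, 0.70 at 13 to 23 Mb and 0.19 at 23 to 33 Mb. Against 1Rb_M it was −0.01 at 3 to 8 Mb. Among chromosomes in no translocation, 13 rose as a whole in 3Rb against both 1Rb crosses, with 40.7% of its 1 Mb bins higher in all 3Rb libraries than in all 1Rb libraries, where chance gives 1.19%; other autosomes in no translocation had up to 34.7% (15), and 10 and 19 had 28.9 and 27.1%. On 8 and 12, where the joined centromere is common to all carriers, the difference between 3Rb and 1Rb_P increased with distance from the centromere over the first 50 Mb (rank correlation 0.456 on 8 and 0.752 on 12, over 1 Mb bins, which are not independent). In the B6 library, γH2AX next to the centromeres of 1, 3, 9 and 14 was like that of 1Rb, at a log2 of −0.44 for the region.

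A candidate explanation for the gain on 1, 3, 9 and 14 is that γH2AX spreads from the joined centromere. The rank correlation of the difference from 1Rb_P with position was negative on all 4, from −0.931 on 3 to −0.527 on 14. For the difference from 1Rb_M it was −0.397 on 14, weaker than the −0.5 asked of each of the 4, so the test leaves this open. Against 1Rb_P, 2 of the 13 other autosomes were also below −0.5 (4 at −0.837 and 13 at −0.713), so distance alone does not set the joined chromosomes apart.

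Both marks may respond to the same event on the joined chromosomes. Over the 19 autosomes, the median proximal change of H3.3 (3Rb minus 1Rb) went with that of γH2AX (3Rb minus 1Rb_P), with Pearson r = 0.811 (permutation p = 9e-05) and Spearman rho = 0.639 (permutation p = 0.00372). Without the 2 chromosomes farthest from the median, 9 and 1, r was 0.649 (permutation p = 0.00565) and rho 0.498 (permutation p = 0.0436). Without 1, 3, 9 and 14, r was 0.685 (permutation p = 0.00419) and rho 0.507 (permutation p = 0.0566). Over the 13 autosomes in none of the translocations, without 8 and 12 as well, r was 0.400 (permutation p = 0.174) and rho 0.258 (permutation p = 0.394), so no relation was shown outside the joined chromosomes. H3.3 was profiled in the 1Rb_M cross, and with the γH2AX change against 1Rb_M the values were r = 0.778 (permutation p = 0.00034) and rho = 0.486 (permutation p = 0.0354) over the 19. Without 9 and 1 they were 0.577 (permutation p = 0.0196) and 0.284 (permutation p = 0.269), without 1, 3, 9 and 14 0.430 (permutation p = 0.11) and 0.225 (permutation p = 0.421), and over the 13 0.311 (permutation p = 0.299) and 0.132 (permutation p = 0.669). By rank, the relation with 1Rb_M did not pass without 9 and 1. The 2 marks come from different libraries and ages, and chromosomes of one library are not independent replicates.

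H3.3 may be gained where γH2AX is enriched in the same cross: in 1Rb against Cg the median proximal change was 0.158 on 8 and 0.109 on 12, above that of every other autosome, of which 7 was highest at 0.0385. This ranking restates the gain on 8 and 12 already seen, so it is no separate test of a link between the marks. Parental strain was not separated from the translocation here.

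Each comparison of 3 with 3 libraries allows 10 splits, so a share under 0.05 cannot be reached, and the counts are given without a verdict on chance. For H3.3 windows, 3Rb against Cg gave 5064 calls against at most 2 in the other splits (1 of 10 splits as large), and 3Rb against 1Rb 3225 against 0 (1 of 10); for chromosomes these were 3 against 0 and 1 against 0 (1 of 10 each). For γH2AX, 3Rb against 1Rb_M gave 20396 windows and 9 chromosomes against 0 and 0, and 3Rb against 1Rb_P 12315 and 8 against 0 and 0 (1 of 10 each). For H3.3 1Rb against Cg, 2042 windows and 1 chromosome compared with 5523 and 13 in the split that sets 1Rb replicate 1 with Cg replicates 2 and 3 (2 of 10 each), which points to a structure of these libraries: the CV of counts over windows was 36.6, 37.9 and 39.0% in those 3 and 42.2 to 42.8% in the other 3. For γH2AX 1Rb_M against 1Rb_P, 880 windows and 0 chromosomes compared with 1280 and 2 in other splits (2 of 10 and 10 of 10), the 1280 with 1Rb_M replicates 1 and 3 and 1Rb_P replicate 1 on one side.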
